A study of Mus musculus with 16 samples.

How the data were processed

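Striatal RNA of 16 mice aged 13 months was sequenced, 4 mice in each of 4 groups. The groups combine the genotype, control or BACHD, with the injected virus, control or Foxp2. BACHD mice carry a bacterial artificial chromosome with a mutant human huntingtin gene. They are a model of Huntington disease. The virus type, the time between injection and harvest and the species of the delivered Foxp2 sequence are not given in the sources used here. Per the labels' protocols, RNA was extracted with the RNeasy Lipid Tissue kit, libraries were made with the Clontech SMARTer chemistry, and pooled bar-coded libraries were sequenced on the Illumina HiSeq platform. Whether the read counting used strand is not given in the sources used here, so reads from overlapping genes cannot be assigned with certainty. No sequencing batch or day is given in the labels.

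The authors deposited 1 table of read counts per gene for each mouse, with 24421 gene symbols and 5 closing lines that sum the reads not assigned to a gene. The submitters' processing notes name STAR 2.4.0, HTSeq, DESeq2 and the genome build mm10, and the count tables have the form of HTSeq output. The counts are whole numbers and are not normalized. The authors also deposited 3 tables of their own comparisons, each with a log2 fold change and an adjusted p-value per gene. Their columns have the form of DESeq2 output, and DESeq2 is among the tools that the submitters' processing notes name. The log2 fold changes and p-values in those deposited tables were read only to set them beside the values computed here. Gene symbols were used as deposited, and 24335 of the 24421 were found in the GENCODE M21 or RefSeq gene tables. Coordinates are those of GENCODE M21 on GRCm38, which is mm10, counted from 1.

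Reads assigned to genes ranged from 2660395 (BACHD+Con mouse 4) to 3669748 (Con+Foxp2 mouse 4) per library, with a median of 3014099.5. They made up 22.5% to 24.7% of the listed reads. Reads outside annotated features made up 38.7% to 43.4%, reads with more than a single alignment 33.8% to 37.2%, and ambiguous reads 0.227% to 0.260%. These 5 summary lines were left out of library sizes and tests. Between 15559 and 16580 genes had reads in a library. At this depth 3 counts in 1 library, the floor used here for genes at 0, corresponded to 0.818 to 1.13 CPM, the unit of reads scaled to a common library total. Mean depth per group ranged from 2894572 ± 160166 (SD, n = 4) gene reads in BACHD+Con to 3190184 ± 322161 in Con+Foxp2. Reads carry no molecular identifiers, so floors and counting intervals cover counting error only. All 120 pairs of libraries differed by more than counting error, with chi-square values per degree of freedom of at least 4.41, and 0 pairs were identical. Y-linked reads were present in all 16 libraries, at 116 to 254 CPM in sum, and Xist was at 0.331 to 10.6 CPM.

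The groups, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined, and the label text states 4 mice per group. The counts as deposited were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Libraries were scaled by trimmed mean of M values, low genes were removed with filterByExpr, and 13563 genes were tested. A single fit of all 16 libraries with a mean per group left 12 residual degrees of freedom. Tests were two-sided, adjusted by Benjamini-Hochberg over all tested genes, and called at an adjusted p under 0.05. The comparisons were the Foxp2 virus against the control virus in each genotype, BACHD against control mice under each virus, and the interaction of genotype and virus. CPM values use the scaled library sizes and are given as mean ± SD over 4 mice. Where all libraries of a group had 0 reads, the fold is a lower bound against 3 counts over that group. With 1 to 3 reads in a group, the ratio is given with its exact 95% counting interval.

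Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01, and adjustment over the lists within a comparison. Of 36 lists fixed beforehand (pathways, striatal neuron classes and markers of other cells that a striatal dissection could hold), 33 had at least 5 tested members. The 3 others, for T and NK cells, B and plasma cells and red blood cells, had 1 tested member each and gave no test. Counts of list members past the threshold are given over all genes and after adjustment over the list alone. The named genes were a panel of 14 (Foxp2, Htt, Foxp1, Foxp4, Drd1, Drd2, Adora2a, Penk, Tac1, Pdyn, Ppp1r1b, Pde10a, Scn4b and Gfap). To these were added the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 1 and groups that do not overlap. Where fewer than 6 passed, all called genes were taken, and predicted genes with Gm or Rik names were left out. The 3 members with the lowest p of each called list completed the rule, and other genes named were chosen after their values were seen. Single values of a few genes are not reported here. Exact permutation tests of 4 against 4 mice have 70 splits and cannot give a two-sided p below 0.0286.

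The procedure was tested on simulated counts drawn from the real means and library sizes. In the simulated comparison of the Foxp2 virus in control mice (13339 genes), 5 of 66 genes changed 1.5-fold were recovered, 33 of 67 changed 2-fold and 53 of 66 changed 4-fold, with 4 false calls among 95. In the simulated comparison of the Foxp2 virus in BACHD mice (13333 genes), 8 of 66, 22 of 65 and 54 of 65 were recovered, with 2 false calls among 86. With no simulated change (13320 genes), 0 genes and 0 lists were called. Each gene was drawn on its own, so the simulation does not test the lists against correlation between genes. Other groupings of the real libraries called a median of 3 to 7 lists, depending on the comparison.

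The alternatives were relative log expression factors, no filter on low counts, a mean of at least 20 counts, the replicate number as a block, 1 surrogate variable (sva 3.50.0), a fit of only the groups compared, DESeq2 1.42.0, limma voom with sample quality weights, and leaving out each library in turn. For lists they were camera with an estimated correlation and fry. Further alternatives were chosen after the data were seen: a score of cortical markers as a covariate, that score with a choroid plexus score, and a fit without the 3 libraries lowest in cortical markers. Ranges of list medians over the alternatives cover only the main fit, the fits with 1 library left out and these further fits. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The labels do not say that a replicate number marks a shared litter, day or batch, so the numbers were not used to pair mice.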

Results

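The striatum, the input nucleus of the basal ganglia and the region most affected in Huntington disease, was profiled by RNA sequencing in 16 mice aged 13 months. Control mice and BACHD mice, which carry a mutant human huntingtin transgene, had been injected with a control virus or a virus for overexpression of Foxp2, a forkhead transcription factor expressed in striatal projection neurons. The 4 groups of 4 mice are called Con+Con, Con+Foxp2, BACHD+Con and BACHD+Foxp2, with the genotype first and the virus second. Each library held 2660395 to 3669748 reads assigned to genes. Values are CPM, mean ± SD over 4 mice, and adjusted p is that of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13563 genes unless another test is named.

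The delivered gene was measured first, as a check of the virus labels. Foxp2 (chromosome 6, 14901349 to 15441977, GRCm38) rose in every mouse given the Foxp2 virus. In control mice its level went from 118 ± 26.7 to 4010 ± 431 CPM, 34.1-fold (log2 fold change 5.09, SE 0.19, adjusted p = 1.04e-14). In BACHD mice it went from 119 ± 28.6 to 1600 ± 288 CPM, a log2 fold change of 3.75 (SE 0.18, adjusted p = 2.39e-12). In both genotypes the 4 Foxp2-virus libraries lay above the 4 control-virus libraries (exact permutation p = 0.0286, the smallest that 4 against 4 can give). Between the genotypes Foxp2 did not pass the test under the control virus (log2 fold change 0.01, adjusted p = 1). Under the Foxp2 virus it was 2.52-fold lower in BACHD than in control mice (log2 fold change -1.33, SE 0.16, adjusted p = 9.64e-05). The lowest Con+Foxp2 library (3500 CPM) lay above the highest BACHD+Foxp2 library (1930 CPM), so the virus comparisons in the 2 genotypes were made at different Foxp2 levels. Whether endogenous and delivered transcripts both contribute to these reads cannot be read from counts per gene. Foxp1 and Foxp4, the related forkhead factors expressed in the brain, did not pass the test. Foxp1 was at 472 ± 107 and 413 ± 20.9 CPM in control mice (adjusted p = 0.871).

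**Figure D1:**
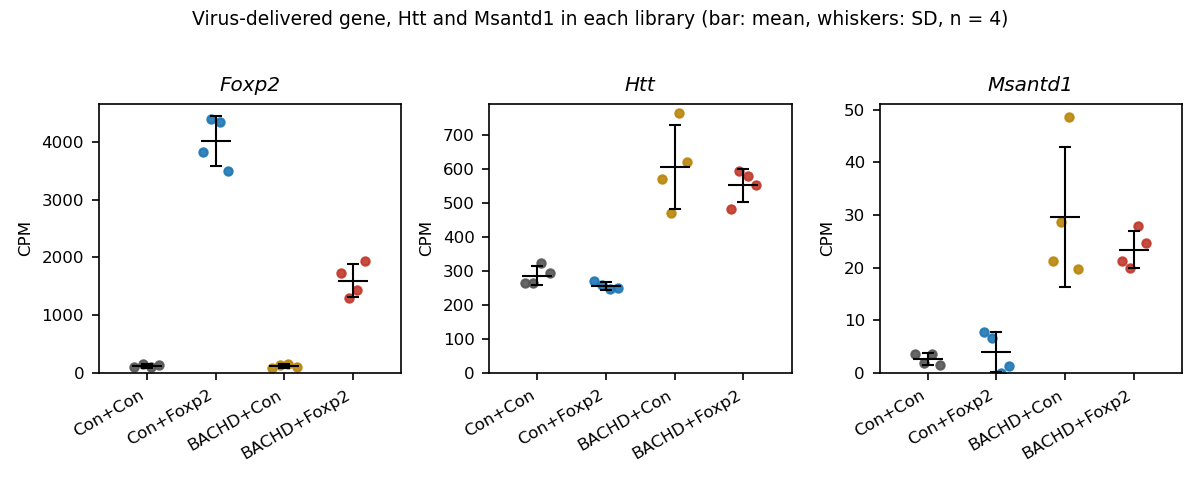
CPM of Foxp2, Htt and Msantd1 in each library (points), with the mean (bar) and SD (whiskers) of the 4 mice per group; all axes are linear and start at 0. Foxp2 averaged 4010 CPM in Con+Foxp2 and 1600 CPM in BACHD+Foxp2 against 118 and 119 CPM under the control virus, and Htt and Msantd1 were higher in BACHD mice.

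In control mice, 4 transcription factor genes with few or no reads under the control virus rose with the Foxp2 virus, while the collagen genes Col4a1 and Col4a2 and the phosphodiesterase gene Pde2a fell. Foxf1, a forkhead factor of developing mesenchyme, rose from 0.956 ± 0.869 to 19.1 ± 5.74 CPM, 18.9-fold (adjusted p = 0.00602). Pax7, a paired-box factor of muscle and midbrain progenitors, had 0 reads in Con+Con and 111 reads in Con+Foxp2, at least 35.4-fold higher (adjusted p = 0.0139). Cdx2, a caudal homeobox factor of the embryonic gut, had 0 and 65 reads, at least 20.7-fold higher (adjusted p = 0.0178). Pou4f1, a POU factor of sensory and habenular neurons, went from 0.73 ± 0.477 to 9.89 ± 6.42 CPM (adjusted p = 0.0263). In all, 19 genes rose and 12 fell. At an unadjusted p under 0.05 there were 955 genes, where 678 would be expected by chance.

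The rise with the lowest p after Foxp2 was that of Col23a1, a membrane-spanning collagen, from 10.2 ± 6.76 to 126 ± 24 CPM, 12.1-fold (log2 fold change 3.60, SE 0.31, adjusted p = 4.17e-07). Several called genes outside the naming rule were chosen after their values were seen. Among them, Cdh4 (R-cadherin, a cell adhesion molecule) rose from 20.3 ± 3.08 to 61.3 ± 6.01 CPM and Frmpd1, a scaffold protein, from 24 ± 9.29 to 70.2 ± 8.85 CPM (adjusted p = 0.00181 for both). Elfn1, a synaptic adhesion protein best known from interneurons, rose from 27.7 to 70.7 CPM (adjusted p = 0.00792). Rab3b, a GTPase of synaptic vesicles, rose from 28.8 to 57.1 CPM (adjusted p = 0.0139). The AP-1 subunit Jun rose from 55.9 to 108 CPM (adjusted p = 0.0366), and Kcnj10, the inward rectifier potassium channel of astrocytes, from 261 to 415 CPM (adjusted p = 0.0251).

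Among the falls, Col4a1 and Col4a2, the major chains of basement membrane collagen, are a divergent gene pair on chromosome 8 (11198423 to 11312826 and 11312805 to 11449287). Col4a1 fell from 91 ± 14.7 to 34.7 ± 2.86 CPM, 2.62-fold (adjusted p = 0.00411), and Col4a2 from 147 ± 17.6 to 60 ± 3.05 CPM, 2.44-fold (log2 fold change -1.29, SE 0.14, adjusted p = 3.15e-05). Pde2a, a cGMP-stimulated phosphodiesterase abundant in the striatum, fell from 761 ± 173 to 413 ± 49.9 CPM (adjusted p = 0.00341). Dnttip1, a subunit of a histone deacetylase complex, fell from 51.1 to 19.9 CPM (adjusted p = 0.0125), and Parn, a poly(A)-specific ribonuclease, from 82 to 35.5 CPM (adjusted p = 0.00181). The kinase Map2k5 fell from 73.9 to 35.6 CPM (adjusted p = 0.0173). Dgki, a diacylglycerol kinase, fell from 297 to 179 CPM, and Cacna2d3, a calcium channel subunit, from 414 to 224 CPM (adjusted p = 0.0141 and 0.0226). Of the named calls, 9 passed with each of the 8 libraries left out in turn: Foxp2, Foxf1, Col23a1, Cdh4, Frmpd1, Parn, Col4a1, Col4a2 and Pde2a. The count of called genes was 10 without Con+Foxp2 mouse 2, 12 without Con+Con mouse 2, and 14 without Con+Con mouse 4 or without Con+Foxp2 mouse 3. Without those same mice, in that order, the adjusted p of Pax7 was 0.0749, 0.0688, 0.0562 and 0.0517 (4.78e-05 to 0.0749 over all its alternatives), and Cdx2 and Pou4f1 were each lost without 5 of the 8 libraries. DESeq2 called 79 genes, all 31 among them, and 19 of the 31 remained without the 3 libraries lowest in cortical markers.

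**Figure D2:**
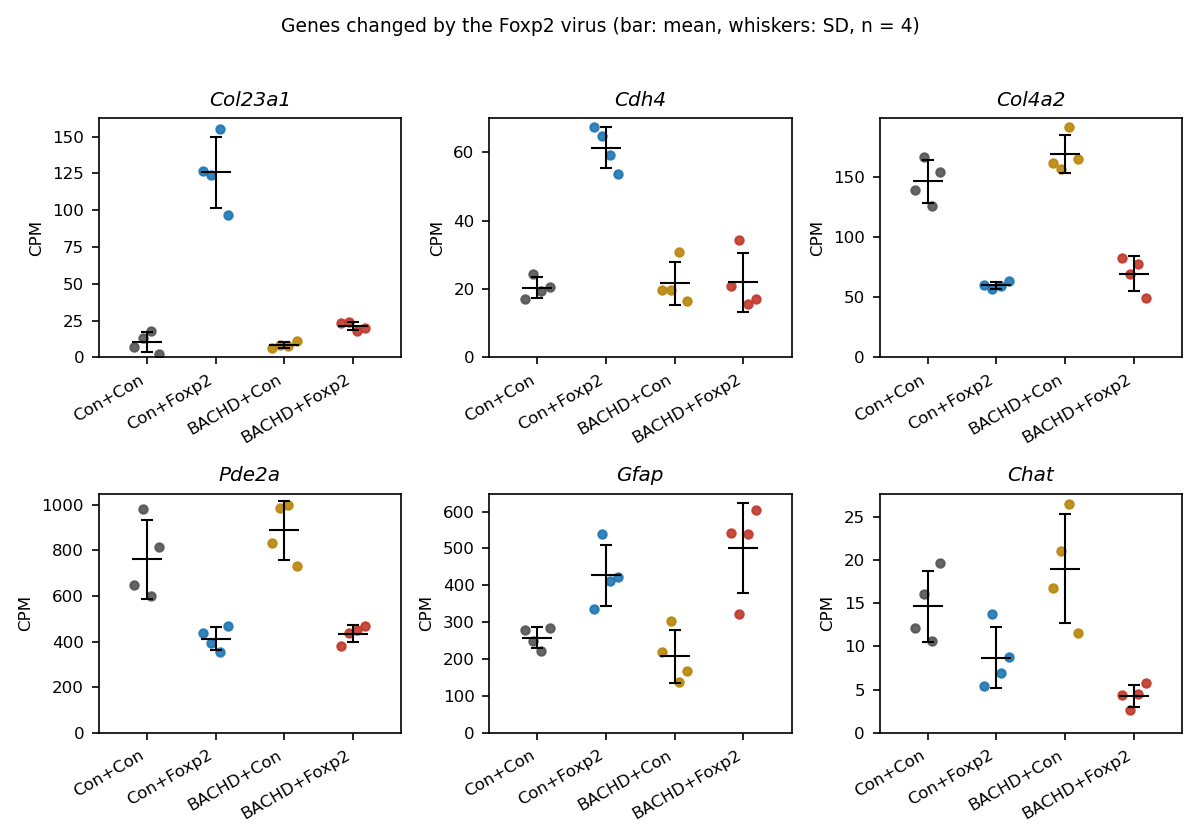
CPM of 6 genes called for the Foxp2 virus in control mice (Col23a1, Cdh4), in BACHD mice (Gfap, Chat) or in both (Col4a2, Pde2a), per library (points) with the mean (bar) and SD (whiskers) of 4 mice; all axes are linear and start at 0. Col23a1 and Cdh4 were at 126 and 61.3 CPM in Con+Foxp2 and at 21.5 and 22 CPM in BACHD+Foxp2, while Col4a2 and Pde2a were lower in both Foxp2-virus groups.

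Across gene lists, markers of striatal interneurons were lower and beta protocadherins, antigen presentation genes and microglial genes were higher with the Foxp2 virus in control mice. The beta protocadherins are neuronal surface proteins of a cluster of 21 similar genes on chromosome 18 (37294812 to 37524479). All 21 were higher, with a median log2 fold change of 0.63 (camera adjusted p = 8.73e-13). Over all genes 2 passed, Pcdhb18 (11.2 ± 3.05 to 31.2 ± 6.2 CPM) and Pcdhb3 (8.75 ± 2.58 to 22.1 ± 3.66 CPM), and 8 did when adjusted over the list alone. Reads that match several members are left out by the authors' counting, so levels of single members are uncertain. The mean of the list was 3.42 ± 0.093 log2 CPM in Con+Con and 4.14 ± 0.164 in Con+Foxp2, with no overlap (exact permutation p = 0.0286, 0.135 when adjusted over the lists). Antigen presentation genes, which encode MHC molecules and their loading machinery, were higher in 12 of 12 (median 0.77, camera adjusted p = 1e-05). Over all genes 0 of them passed by edgeR, and 3 did when adjusted over the list alone. B2m, the light chain of MHC class I, was at 36.9 and 64.9 CPM (adjusted p = 0.119) and H2-D1, an MHC heavy chain, at 10.7 and 22.2 CPM (adjusted p = 0.208). Microglial genes were higher in 13 of 17 (median 0.33, camera adjusted p = 0.00107; 2 adjusted over the list alone and 0 over all genes). The lysosomal protease Ctss was at 59.3 and 86.2 CPM (adjusted p = 0.282) and the complement gene C1qc at 8.41 and 16.6 CPM (adjusted p = 0.369).

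The interneuron list was lower in 12 of 13 members (median -0.93, -1.31 to -0.66 over its alternatives, camera adjusted p = 2.24e-07; 3 adjusted over the list alone and 0 over all genes). Slc17a8, a vesicular glutamate transporter of cholinergic interneurons, was at 13.2 and 3.24 CPM (adjusted p = 0.115), Pvalb of fast-spiking interneurons at 48.5 and 20.8 CPM (adjusted p = 0.342), and the choline transporter Slc5a7 at 28.9 and 9.43 CPM (adjusted p = 0.424). These 4 lists were also called with an estimated correlation, and 8 further lists were not. Projection neuron markers were lower in 26 of 26 (median -0.45, camera adjusted p = 2.92e-09, adjusted p = 0.38 with an estimated correlation), 14 of them adjusted over the list alone and 0 over all genes. Scn4b, a sodium channel subunit, was at 499 ± 161 and 305 ± 54.1 CPM (adjusted p = 0.156), and the tyrosine phosphatase Ptpn5 at 490 and 324 CPM (adjusted p = 0.182). Genes that fall in mouse models of Huntington disease, which share many members with that list, had a median of -0.45 (25 of 28 lower; 15 adjusted over the list alone; adjusted p = 0.38 with an estimated correlation). Direct and indirect pathway markers had medians of -0.39 and -0.35 (adjusted p = 0.389 and 0.38 with an estimated correlation). The dopamine receptors Drd1 (138 and 99.9 CPM) and Drd2 (103 and 76 CPM), Adora2a (102 and 58.6 CPM), Tac1 (88.5 and 54.3 CPM), Penk (828 and 633 CPM), Ppp1r1b (574 and 422 CPM) and Pde10a (1430 and 1040 CPM) did not pass over all genes.

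Of the remaining 4 lists, astrocyte genes had a median of 0.17 (adjusted p = 0.38 with an estimated correlation), with Kcnj10 as a called astrocytic gene outside the list, and interferon response genes a median of 0.29 (adjusted p = 0.297 with an estimated correlation). Oligodendrocyte genes, which serve myelin, had a median of -0.39 (adjusted p = 0.541 with an estimated correlation). Developmental regulators silenced by Polycomb, a repressive chromatin complex, had 8 of 35 members expressed enough to test. These 8 include Pax7 and Pou4f1, called above as single genes, so the list is not separate from those calls. Their median was 0.37 (adjusted p = 0.295 with an estimated correlation), and the call was lost without Con+Foxp2 mouse 2, the highest in this list (median -0.02, camera adjusted p = 0.0911). Over the alternatives the median ran from -0.02 to 0.78. The list mean was higher by 0.76 log2 CPM, with mouse 2 at 4.33 and the other Con+Foxp2 mice at 3.10 to 3.16. Genes named as FOXP2 targets in earlier work were not called (median 0.01, camera adjusted p = 0.778), nor were immediate early genes (median 0.02, adjusted p = 0.316). As for chance, 5 of the 35 splits of these 8 mice, the real one included, called at least 12 lists, while no other split called more than 4 genes.

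**Figure D3:**
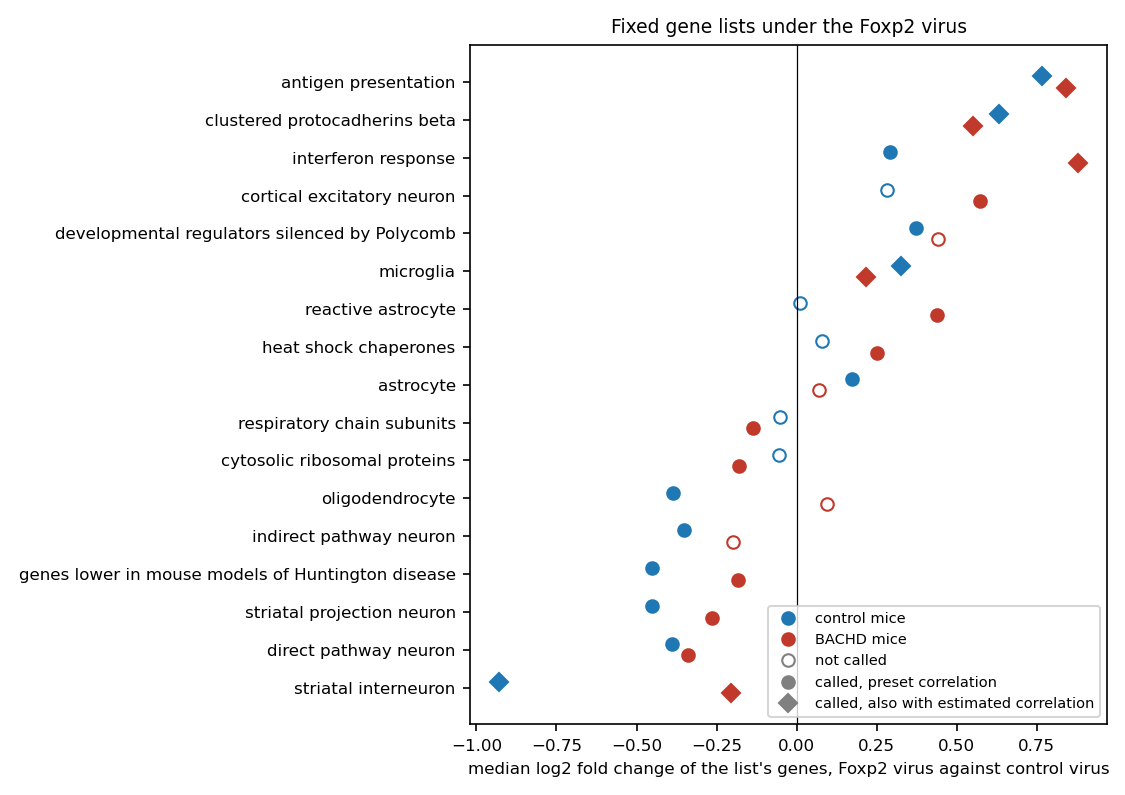
Median log2 fold change of each list called in at least 1 genotype, Foxp2 virus against control virus, in control mice (blue) and BACHD mice (red). Filled symbols were called by camera with the preset correlation, diamonds also with an estimated correlation, and open symbols were not called; interneuron markers were at -0.93 in control mice and -0.21 in BACHD mice, while their list means differed by -0.87 and -0.71 log2 CPM, and antigen presentation genes at 0.77 and 0.84.

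In BACHD mice, Gfap rose with the Foxp2 virus, and Chat, Pde2a and Col4a2 fell. Gfap, the intermediate filament of reactive astrocytes, rose from 207 ± 71.9 to 501 ± 123 CPM, 2.41-fold (log2 fold change 1.27, SE 0.20, adjusted p = 0.00326). Chat, the acetylcholine-synthesizing enzyme of cholinergic interneurons, fell from 19 ± 6.36 to 4.31 ± 1.28 CPM, 4.39-fold (log2 fold change -2.13, SE 0.37, adjusted p = 0.00845). Lyz2, the lysozyme of myeloid cells, rose from 1.81 ± 1.1 to 11.8 ± 7 CPM (adjusted p = 0.0161) and Ctss from 47.8 to 81.7 CPM (adjusted p = 0.0465). Altogether 12 genes rose and 21 fell, and 1048 passed an unadjusted p of 0.05.

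Genes near 0 under the control virus again led the rises by fold. Pou4f1 had 0 reads in BACHD+Con and 99 in BACHD+Foxp2, at least 32.1-fold higher (adjusted p = 0.00276). Jchain, the joining chain of secreted immunoglobulins, had 1 and 135 reads, a ratio of 131 with a 95% counting interval of 23.2 to 5230 (adjusted p = 0.0118). Styk1, a kinase-like membrane protein, had 1 and 50 reads, a ratio of 48.6 with an interval of 8.34 to 1960 (adjusted p = 0.0442). Tex15, a meiosis gene, rose from 0.757 to 10.6 CPM (adjusted p = 0.0383), Jun from 41.9 to 93.5 CPM (adjusted p = 0.00845) and Rab3b from 29.8 to 57.4 CPM (adjusted p = 0.0182). Of the falls in BACHD mice, Col4a2 went from 169 ± 15.8 to 69.8 ± 14.8 CPM (2.42-fold, adjusted p = 5.36e-05) and Pde2a from 889 ± 130 to 435 ± 38 CPM (adjusted p = 0.000716). Dnttip1 fell from 75.1 ± 2.8 to 24.1 ± 8.61 CPM (adjusted p = 0.00221). Hook2, a microtubule adaptor, fell from 37.7 to 11.9 CPM and Mtmr14, a phosphoinositide phosphatase, from 47.7 to 16.3 CPM (adjusted p = 0.00306 for both). Vars2, the mitochondrial valine tRNA synthetase, fell from 45.5 to 20.7 CPM (adjusted p = 0.0182). Dgki (312 to 183 CPM), Map2k5 (72.3 to 37.1 CPM) and Cacna2d3 (423 to 243 CPM) fell as well. Col4a1 was at 92.6 and 50.6 CPM and did not pass (adjusted p = 0.14).

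Of the named calls in BACHD mice, 8 passed with each of the 8 libraries left out: Foxp2, Pou4f1, Gfap, Hook2, Dnttip1, Mtmr14, Col4a2 and Pde2a. The count of called genes was 9 without BACHD+Con mouse 3, 18 without BACHD+Con mouse 2 or BACHD+Foxp2 mouse 4, and 20 without BACHD+Con mouse 1. Without BACHD+Con mouse 3 the adjusted p was 0.0698 for Chat and 0.0747 for Jchain, and Jchain was also lost without BACHD+Con mouse 1 (0.0623) or 2 (0.0524). Lyz2 passed in 4 of the 8 fits with 1 library left out (highest adjusted p = 0.0916), and Ctss, Styk1 and Tex15 in 1 of 8 each (highest 0.179, 0.176 and 0.123). Over all alternatives the adjusted p ran from 0.000394 to 0.2 for Lyz2 and from 0.005 to 0.456 for Ctss. Without the 3 libraries lowest in cortical markers, 2 of them BACHD+Con mice, 5 of the 33 calls remained, and the adjusted p, then the highest of all alternatives tried, was 0.313 for Chat, 0.192 for Jchain, 0.182 for Hook2 and 0.0647 for Pou4f1; the lowest were 9.76e-05, 6.58e-05, 5.04e-06 and 5.19e-06. A fit of the 8 BACHD mice alone called 19 genes, DESeq2 62 and voom 16.

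Interferon response, antigen presentation, beta protocadherin and microglial genes were higher as lists in BACHD mice, and interneuron markers lower. The interferon genes were higher in 13 of 14 (median 0.88, camera adjusted p = 5.53e-09), 4 of them adjusted over the list alone and 0 over all genes. Their list mean was 2.21 log2 CPM in BACHD+Con and 3.13 in BACHD+Foxp2, against 2.82 in Con+Con and 3.22 in Con+Foxp2. The means of the Foxp2-virus groups did not differ past the threshold (exact permutation p = 0.143). The larger difference between viruses in BACHD mice thus goes with a lower control-virus level. The interferon-induced GTPase Gbp3 was at 3.48 and 12.7 CPM (adjusted p = 0.248), the signal transducer Stat2 at 20.8 and 35.3 CPM (adjusted p = 0.217) and Oasl2, an antiviral gene, at 1.45 and 5.48 CPM (adjusted p = 0.319). Antigen presentation genes were higher in 12 of 12 (median 0.84, camera adjusted p = 1.51e-05; 2 adjusted over the list alone and 0 over all genes), with B2m at 41 and 66.3 CPM (adjusted p = 0.248). Beta protocadherins were higher in 17 of 21 (median 0.55, camera adjusted p = 5.69e-07; 4 adjusted over the list alone and 0 over all genes), with Pcdhb18 at 13.8 and 27.1 CPM (adjusted p = 0.272). Microglial genes had a median of 0.22 (camera adjusted p = 0.00216), and Ctss passed both over all genes and as the 1 member adjusted over the list alone. Interneuron markers were lower in 13 of 13, with a median of -0.21 and a mean of -0.65 (camera adjusted p = 0.000356). Chat passed over all genes, 3 members did adjusted over the list alone, and Slc5a7 was at 24 and 7.41 CPM (adjusted p = 0.388). Over the alternatives the medians ran from 0.698 to 1.628 for interferon and from 0.603 to 1.135 for antigen presentation genes, both highest without the 3 libraries lowest in cortical markers. They ran from 0.406 to 0.645 for beta protocadherins, 0.142 to 0.291 for microglial genes and -0.685 to -0.133 for interneuron markers. These 5 lists were also called with an estimated correlation. Their means overlapped between the groups for microglial genes (exact permutation p = 0.0571) and interneuron markers (0.0857), and not for the other 3 (0.0286 each, 0.135 when adjusted over the lists). No other split of these 8 mice into 4 and 4 called 33 genes (the highest was 2). For lists the highest other split called 12, and with 1 library left out the real count ran from 11 to 16.

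The other 8 called lists in BACHD mice were not called with an estimated correlation. Reactive astrocyte genes were higher in 15 of 17 (median 0.44, adjusted p = 0.168 with an estimated correlation); Gfap passed, and the intermediate filament Vim was at 45 and 66.7 CPM (adjusted p = 0.5). Heat shock chaperones had a median of 0.25 (adjusted p = 0.173 with an estimated correlation), with Hsp90aa1 at 143 and 185 CPM. Respiratory chain subunits were lower in 46 of 61 (median -0.14, adjusted p = 0.173 with an estimated correlation), 5 of them adjusted over the list alone. Cox4i1, a subunit of complex IV, was at 289 and 216 CPM (adjusted p = 0.0575). Cytosolic ribosomal proteins were lower in 34 of 48 (median -0.18, adjusted p = 0.124 with an estimated correlation), 1 of them adjusted over the list alone. Projection neuron markers had a median of -0.27 (25 of 26 lower; 0 adjusted over the list alone; adjusted p = 0.596 with an estimated correlation). Direct pathway markers had a median of -0.34 and Huntington model genes a median of -0.18 (adjusted p = 0.505 and 0.732 with an estimated correlation). The median of the Huntington model list was 0.03 with the cortical score as a covariate. Markers of cortical excitatory neurons were higher in 14 of 16 (median 0.57, adjusted p = 0.596 with an estimated correlation), with the neurogenic factor Neurod2 at 22.8 and 55.9 CPM (adjusted p = 0.674), while Lamp5, a member of that list, fell. That list was at -0.07 without the 3 libraries lowest in its own markers, and its call was lost without BACHD+Con mouse 2 (camera adjusted p = 0.178) or mouse 3 (0.142), within a range of 5.05e-06 to 0.98 over its alternatives.

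Setting the virus comparisons of both genotypes side by side asked whether Foxp2 acted alike in BACHD and control mice. They share no library. Called in both were 4 rises (Foxp2, Jun, Pou4f1 and Rab3b) and 7 falls (Col4a2, Pde2a, Dnttip1, Dgki, Cacna2d3 and Map2k5 among them), where independent lists would share 0.0168 and 0.0186. Of 30 genes called in control mice other than Foxp2, 27 had the same sign in BACHD mice and 19 of these an unadjusted p under 0.05. Of the other 3, Pax7 (5 and 0 reads) and Elfn1 (26.9 and 26.8 CPM) had no measurable direction in BACHD mice. All 32 genes other than Foxp2 called in BACHD mice had the same sign in control mice, 30 with an unadjusted p under 0.05. Gfap, for example, was at 258 and 427 CPM in control mice (adjusted p = 0.182), and Chat at 14.6 and 8.73 CPM (adjusted p = 0.694). Across 13563 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.257 and Spearman's rho = 0.222. Simulated unchanged groups gave a mean r of 0.001 (lowest -0.020, highest 0.023). Each gene was drawn on its own there, so differences between libraries that many genes share are absent. The virus labels were also permuted within each genotype in all 4900 ways, on differences of mean log2 CPM. The observed r was 0.254 on that scale, the permuted values ran from -0.341 to 0.341, and the exact two-sided p was 0.00735. The r of the fitted log2 fold changes was 0.251 without Foxp2 and 0.137 without the 3 libraries lowest in cortical markers.

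**Figure D4:**
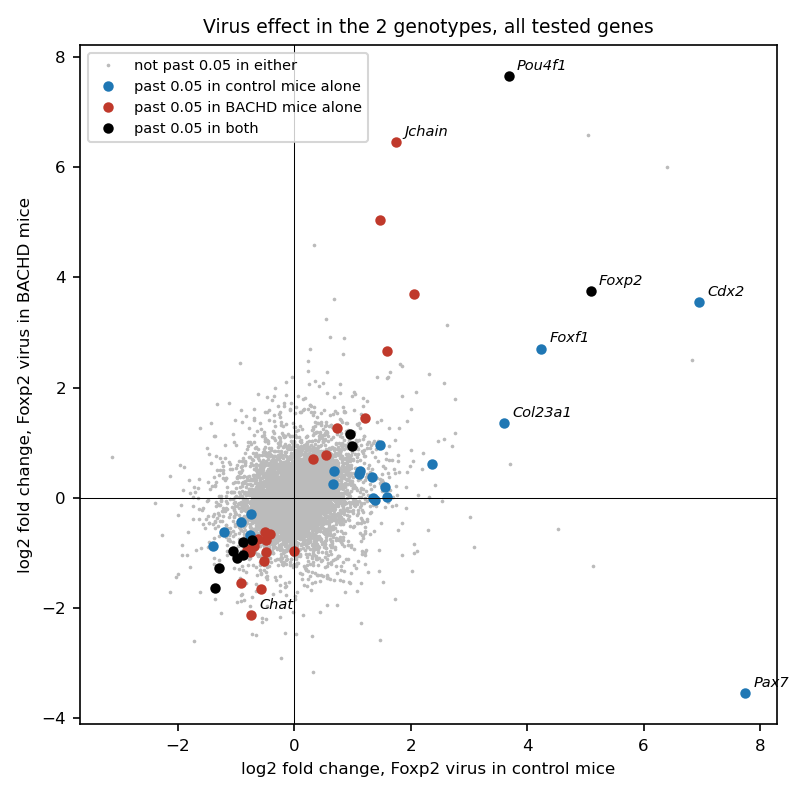
Log2 fold changes of all tested genes for the Foxp2 virus in control mice (x axis) and in BACHD mice (y axis), coloured by where a gene passed an adjusted p of 0.05. Foxp2 and Pou4f1 lie to the upper right, and fitted values of genes with 0 reads in a group, such as Pax7, Cdx2 and Pou4f1, depend on the prior count.

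Under the Foxp2 virus, 7 genes were lower in BACHD than in control mice and 1 was higher. Besides Foxp2 itself, Col23a1 was at 126 ± 24 CPM in Con+Foxp2 and 21.5 ± 2.81 CPM in BACHD+Foxp2, 5.84-fold lower (log2 fold change -2.55, SE 0.29, adjusted p = 7.29e-05). Frmpd1 was at 70.2 and 20.6 CPM (adjusted p = 0.000402), Cdh4 at 61.3 and 22 CPM (adjusted p = 0.0063) and Elfn1 at 70.7 and 26.8 CPM (adjusted p = 0.00851). Pax7 had 111 reads in Con+Foxp2 and 0 in BACHD+Foxp2, at least 34.1-fold lower (adjusted p = 0.0266). Cdh4 was at 21.7 and 22 CPM without and with the Foxp2 virus in BACHD mice (adjusted p = 0.994), Frmpd1 at 17.9 and 20.6 CPM (adjusted p = 0.909), Elfn1 at 26.9 and 26.8 CPM (adjusted p = 1) and Col23a1 at 8.42 and 21.5 CPM (adjusted p = 0.118). Foxf1 had 3 and 23 reads in BACHD mice, a ratio of 7.46 with a counting interval of 2.25 to 38.8, and Cdx2 3 and 41 reads, a ratio of 13.3 with an interval of 4.24 to 67.1. Neither passed in BACHD mice, and Foxf1 did not pass between the Foxp2-virus groups (19.1 and 1.9 CPM, adjusted p = 0.0679). The gene that was higher was Htt. The calls of Foxp2, Col23a1, Frmpd1 and Htt held with each library left out, whereas 4 genes were called without BACHD+Foxp2 mouse 4, when Cdh4 had an adjusted p of 0.0618 and Elfn1 of 0.0711. Over all alternatives they ranged from 1.77e-05 to 0.0618 and from 5.18e-05 to 0.0726, the last without Con+Foxp2 mouse 2, and Pax7 from 9.72e-05 to 0.191. Pax7 was lost without any 1 of the 8 libraries (adjusted p = 0.0789 to 0.173). The single list called was that of astrocyte genes (median -0.18, camera adjusted p = 0.00743, adjusted p = 0.867 with an estimated correlation), and 31 of 35 splits of these 8 mice called at least 1 list.

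The difference of the virus effects between genotypes was then tested itself, as the interaction of genotype and virus. No gene passed with edgeR (0 genes, and 516 at an unadjusted p under 0.05, where 678 would be expected by chance). Voom called 0 genes and DESeq2 3. The 3 were Foxp2, Col23a1 and Pax7. With edgeR the interaction was -1.34 (SE 0.23, adjusted p = 0.077) for Foxp2, -2.25 (adjusted p = 0.362) for Col23a1, -1.58 (adjusted p = 0.386) for Cdh4 and -1.35 (adjusted p = 0.809) for Frmpd1 and for Elfn1. As lists, interferon response and oligodendrocyte genes were called, with medians of 0.71 and 0.47 (camera adjusted p = 0.00491 for both, and adjusted p = 0.216 and 0.991 with an estimated correlation). At least 2 lists were called in 92 of 100 groupings of the libraries, the real one included.

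Without the Foxp2 virus, the BACHD genotype at 13 months changed 2 genes past the threshold, the huntingtin gene and its neighbour. Htt (chromosome 5, 34761740 to 34912534) rose from 286 ± 27.8 to 607 ± 123 CPM, 2.12-fold (log2 fold change 1.08, SE 0.12, adjusted p = 9.39e-05). Reads of the human transgene that align to the mouse gene would be counted in it. Msantd1, which starts at 34908012 and ends at 34923839, shares 4523 bases with the end of Htt on the same strand. It rose from 2.62 ± 1.07 to 29.6 ± 13.3 CPM (log2 fold change 3.46, SE 0.55, adjusted p = 0.016). Under the Foxp2 virus Htt was at 256 ± 11.8 and 553 ± 49.5 CPM, 2.16-fold higher in BACHD mice (adjusted p = 6.36e-05), and Msantd1 at 3.91 ± 3.8 and 23.4 ± 3.55 CPM (adjusted p = 0.0768; exact permutation p = 0.0286). For the Foxp2 virus Htt did not pass in either genotype (log2 fold change -0.16 in control and -0.14 in BACHD mice, adjusted p = 0.871 and 0.862). The call of Msantd1 was lost without Con+Con mouse 1, 2 or 4 (adjusted p = 0.07, 0.143 and 0.139), without BACHD+Con mouse 3 (0.127), with voom (0.507) and without the 3 libraries lowest in cortical markers (0.988, the highest of its alternatives; the lowest was 3.89e-07). At least 2 genes were called in 4 of the 35 splits of these 8 mice, the real one included (highest other 355).

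None of the named projection neuron genes that are lower in models of Huntington disease passed between BACHD and control mice under the control virus. Pde10a was at 1430 and 1280 CPM, Scn4b at 499 and 388 CPM, Drd1 at 138 and 133 CPM, Drd2 at 103 and 93.9 CPM, Adora2a at 102 and 83.3 CPM and Penk at 828 and 854 CPM (adjusted p = 1 for each). Pdyn, the prodynorphin gene of the direct pathway, was at 56.4 and 90.4 CPM (adjusted p = 1). As lists, projection neuron markers and Huntington model genes were not called (medians -0.01 and -0.09, camera adjusted p = 0.442 for the second). Of 3 fits for tissue makeup, chosen after the data were seen, camera with the preset correlation called both lower with the cortical and choroid scores as covariates (medians -0.13 and -0.20, adjusted p = 0.00574 and 0.00128). It called neither with the cortical score alone (adjusted p = 0.195 and 0.0589) nor without the 3 libraries lowest in cortical markers (0.289 and 0.34). Both were called higher under the Foxp2 virus with either covariate fit, and for the interaction in 2 of the 3 fits (projection neuron markers) and in 3 of 3 (Huntington model genes). With an estimated correlation none of the 3 fits called either list in this comparison (lowest adjusted p = 0.651), under the Foxp2 virus (0.839) or for the interaction (0.744). Foxp2, Foxp1 and Foxp4 differed by 1.01-fold, 1.08-fold and 1.03-fold. Of the lists, 9 were called, 1 up and 8 down, and interferon response genes alone were also called with an estimated correlation (median -0.63, -1.062 to -0.345 over its alternatives, 12 of 14 lower, camera adjusted p = 8.95e-06). None of them passed over all genes. The viral RNA sensors Ddx58 and Ifih1 were at 11.8 and 5.62 CPM and at 8.49 and 3.62 CPM, and the list mean did not pass a test of its own (exact permutation p = 0.0571). The same BACHD+Con libraries enter the virus comparison in BACHD mice and the interaction, so the interferon values there are not separate results. The adjusted p with an estimated correlation was 0.613 for beta protocadherins (median 0.27) and meningeal genes (median -0.71). It was 0.694 for astrocyte (median -0.08), choroid plexus (median -0.50, and 0.36 without Con+Con mouse 1) and thalamic and septal genes (median -0.69), 0.657 for heat shock chaperones (median -0.11), 0.73 for oligodendrocyte genes (median -0.30) and 0.342 for the Y-linked genes and Xist (median -0.36; 1 adjusted over the list alone). At least 9 lists were called in 10 of the 35 splits, the real one included. Only 2 lists were called without BACHD+Con mouse 3 and 5 without Con+Con mouse 1.

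Whether the Foxp2 virus moved the genes that differ in BACHD mice back towards control was asked by correlating the effect of the genotype with that of the virus in BACHD mice. The 2 effects share the BACHD+Con libraries, which gives a negative correlation with no effect at all. The observed r was -0.433 across 13563 genes (rho = -0.386), and simulated unchanged groups gave a mean of -0.500 (lowest -0.534, highest -0.482). The covariance was -0.0744 against -0.0709 in the simulation, a difference of -0.00353. The simulated groups again drew each gene on its own. On differences of mean log2 CPM the observed r was -0.406, and 34650 assignments of the libraries gave a mean of -0.498 (-0.705 to -0.222). The exact one-sided permutation p for a correlation as negative was 0.892. With the BACHD+Con mice split 2 and 2, sharing no library, the 6 fitted values of r ranged from -0.025 to 0.142. Neither Htt nor Msantd1 passed for the virus in BACHD mice.

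Markers of other tissue varied between libraries within groups. The mean log2 CPM of cortical excitatory neuron markers ranged from 3.73 (BACHD+Con mouse 3) to 6.60 (Con+Con mouse 3), and Slc17a7, the vesicular glutamate transporter of cortical neurons, from 19.1 to 650 CPM in the same mice. By group the cortical score was 5.20 ± 1.10 in Con+Con, 5.66 ± 0.775 in Con+Foxp2, 4.96 ± 1.37 in BACHD+Con and 5.90 ± 0.433 in BACHD+Foxp2. The 3 libraries below the lowest Foxp2-virus library (4.53) were Con+Con mouse 4 and BACHD+Con mice 2 and 3, all given the control virus. Projection neuron markers were at 8.58, 8.23, 8.56 and 8.30 log2 CPM in the same order of groups, lower in the Foxp2-virus groups, where the cortical score was higher. Ttr, the transthyretin gene of the choroid plexus, ranged from 89.7 to 10100 CPM.

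**Figure D5:**
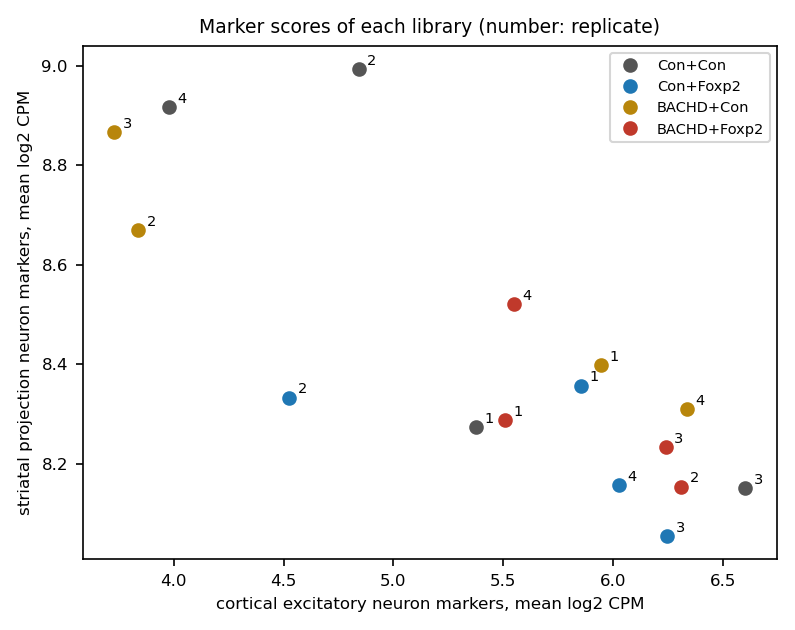
Mean log2 CPM of striatal projection neuron markers (y axis) against that of cortical excitatory neuron markers (x axis) in each of the 16 libraries, with the replicate number beside each point. The cortical score ran from 3.73 in BACHD+Con 3 to 6.60 in Con+Con 3, and the 3 libraries with the lowest cortical scores had the control virus.

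In the authors' deposited table for the Foxp2 virus in control mice, 57 genes were higher and 54 lower at an adjusted p under 0.05 of 14918 genes with a value, and all 31 genes called here were among them. For Foxp2 the authors' deposited table gives a log2 fold change of 4.51, against 5.09 with edgeR and 5.089 with DESeq2 as run here. The reason for the difference was not tested. In BACHD mice the authors' deposited table lists 14 higher and 31 lower, with 30 of the 33 called here. For the BACHD genotype under the control virus the authors' deposited table lists 3 genes, which include Htt and Msantd1.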

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

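The tests in this part on Msantd1, cortical tissue and the Foxp2 level were chosen after the results were seen, and the interaction test was planned. The comparison of each library with the rest of its group takes in genes that were chosen after their values were seen.

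Msantd1 rose together with Htt in BACHD mice. If a constant share of Htt reads were counted for Msantd1, the overlapping gene downstream, its level relative to Htt would be equal in both genotypes. It was 1.2 ± 1.01% of the Htt CPM in the 8 control libraries and 4.54 ± 1.18% in the 8 BACHD libraries. The ratio of 3.78 argues against a constant share as the whole cause. Whether reads of the transgene are counted for Msantd1 at another share than mouse Htt reads was not tested. A transgene that carries both genes with regulatory sequence may raise both, and a change of the mouse gene in BACHD tissue is not excluded. The neighbours Grk4, Nop14, Rgs12 and Add1 did not pass under the control virus (the value farthest from 0 was -0.32, for Grk4), which does not tell these apart, since the extent of the transgene is not given in the sources used here.

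Cortical markers were lowest in 3 control-virus libraries, so tissue from the overlying cortex could bring differences between virus groups. With the cortical score as a covariate 31 of 31 calls in control mice and 27 of 33 in BACHD mice still passed. Without the 3 libraries, 19 of 31 and 5 of 33 passed, with 2 BACHD+Con mice left, so that fewer samples are part of the second count. In control mice the covariate fit argues against cortical tissue as the whole cause of those calls. In BACHD mice the 2 fits differ. Genes called there were 9 without BACHD+Con mouse 3, the lowest in cortical score, and at most 26 without another single mouse. The number of samples is the same in both cases, so the question is not decided for BACHD mice. For the projection neuron list in BACHD mice the median went from -0.27 to -0.077 with the covariate and to -0.037 without the 3 libraries (camera adjusted p = 0.427 and 0.453), as cortical tissue would predict, and the list is not called there. In control mice the same list went from -0.453 to -0.286 with the covariate. It was still called with the preset correlation (camera adjusted p = 4.35e-08). With an estimated correlation the list was not called, either with the covariate (camera adjusted p = 0.436) or without it (0.38).

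Of the 7 genes lower in BACHD+Foxp2 than in Con+Foxp2, 6 are not Foxp2 itself. A virus effect that scales with the Foxp2 level by 1 factor for every gene would put them at the product of the effect in control mice and the Foxp2 ratio on the log2 scale, 0.736. All 6 lay below that product, but they were picked because they differ, and the interaction test called 0 of them with edgeR and 2, Col23a1 and Pax7, with DESeq2, so the test does not decide. A weaker response of BACHD mice as such cannot be told apart from less Foxp2, because the highest BACHD+Foxp2 library held 1930 CPM and the lowest Con+Foxp2 library 3500 CPM. A threshold or cooperative response to the Foxp2 level remains a candidate explanation that was not tested.

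In groups of 4, a library was counted as standing apart when its gap to the nearest other, as a share of the group's range, exceeded Dixon's 95% critical value. Chance gives this in about 1 of 20 groups, so about 33 of the 659 groups examined, and 42 did. The gaps below are given as shares of the range.

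Choroid plexus genes stood apart in BACHD+Con mouse 2, where the list was at 6.89 log2 CPM against 1.92 to 2.59 in its group (gap 0.864), Slc4a5 at 78.3 CPM against 0.336 to 3.08 (0.965), Aqp1 at 12.2 CPM (0.973) and Otx2 at 23.5 CPM (0.901). In BACHD+Foxp2 mouse 3 Slc4a5 was at 54 CPM (0.975), Aqp1 at 16.5 CPM (0.978) and Otx2 at 26.8 CPM (0.926). In Con+Foxp2 mouse 3 the fibrillar collagens Col1a1 (32.2 CPM) and Col1a2 (27.8 CPM) were high (0.839 and 0.842).

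Con+Foxp2 mouse 2 stood apart in Tcf7l2, a marker of thalamic neurons, at 140 CPM against 26.5 to 40.6 (0.876), in the Polycomb list at 4.33 log2 CPM against 3.10 to 3.16 (0.953) and in the ependymal list (0.882). It was also apart in Elfn1 at 106 CPM against 56.7 to 61 (0.913), Rab3b at 74 CPM (0.892), C1qc at 21.6 CPM (0.926) and Rgs12 at 17.7 CPM (0.847).

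Among genes called for the virus, Pou4f1 was at 16.3 CPM in BACHD+Foxp2 mouse 4 against 5.16 to 5.85 (0.938), Jun at 78.3 CPM in BACHD+Foxp2 mouse 1 against 97.6 to 99.8 (0.898), Rab3b at 34.1 CPM in Con+Con mouse 2 (0.951) and Dnttip1 at 79.3 CPM in BACHD+Con mouse 2 (0.942). Protocadherins stood apart as Pcdhb18 at 34 CPM in BACHD+Foxp2 mouse 1 (0.901), Pcdhb20 at 34.9 CPM in BACHD+Con mouse 3 (0.929) and Pcdhga3 at 24.9 CPM in BACHD+Foxp2 mouse 4 (0.951). Glial and immune genes did as Cx3cr1 at 25.9 CPM in Con+Foxp2 mouse 3 (0.889) and at 23.1 CPM in BACHD+Con mouse 2 (0.934), Ugt8a at 45.7 CPM in Con+Foxp2 mouse 1 (0.87) and Ifih1 at 10.5 CPM in BACHD+Foxp2 mouse 4 (0.855). Others were Dnaja1 at 59.5 CPM (0.84) and Rps21 at 34.1 CPM (0.931) in BACHD+Foxp2 mouse 3, Ebf1 at 27.7 CPM in BACHD+Foxp2 mouse 4 (0.895) and Ddx3y at 36.9 CPM in BACHD+Con mouse 3 against 71.1 to 77 (0.855).

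Of the list means, BACHD+Con mouse 3 was high in cytosolic ribosomal proteins (0.928) and low in p53 targets (0.898), and Con+Con mouse 3 was high in presynaptic genes (0.832) and low in activated microglial genes (0.849). In BACHD+Foxp2, mouse 4 was high in Huntington model genes (0.841), mouse 1 high in cholesterol synthesis (0.847) and mouse 2 low in interferon response genes (0.857). Of the read totals, Con+Foxp2 mouse 4 had the most gene reads (0.863), and Con+Foxp2 mouse 1 had 35.8% of reads with more than a single alignment against 34.9% (0.943) and 40.2% outside features against 41.4% (0.945). In BACHD+Foxp2 mouse 1 the 10 most abundant genes took 9.39% of gene reads against 8.12% to 8.26% (0.893).

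The interaction test with the preset correlation called 2 lists, interferon response genes (median interaction 0.711) and oligodendrocyte genes (0.467). Neither call held with an estimated correlation (adjusted p = 0.216 and 0.991), and 92 of 100 groupings of the libraries called at least 2 lists. The list means differed between viruses by 0.397 in control and 0.914 in BACHD mice for interferon, and by -0.351 and 0.041 for oligodendrocyte genes, and exact permutation of the virus labels within each genotype (4900 arrangements) gave p = 0.232 and 0.365.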

How the results depend on the processing

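The cortical and choroid covariates and the fit without the 3 libraries lowest in cortical markers were chosen after the results were seen, and the other alternatives before. Of 246 values of named genes under 4817 alternatives, 4510 kept their side of the threshold, 234 lost a call and 73 gained one. Values that changed sign with a call in either fit numbered 0, and a change of sign with no call was counted as kept. Of 37 called lists under 534 alternatives, 400 kept the call, 130 lost it and 4 reversed. Foxp2 was called under all of them (4.995 to 5.22 in control and 3.63 to 3.90 in BACHD mice with 1 library left out). Relative log expression factors changed no named call. Called genes for the virus in control mice (31) were 75 with no filter, 54 with the cortical covariate, 86 with both covariates, 79 with DESeq2, 49 with voom, and 10 to 46 with 1 library left out; 61.3% of the calls were rises, and 50%, 54.4% and 52% with both covariates, DESeq2 and no filter. For the virus in BACHD mice (33) they were 53 with no filter, 62 with DESeq2, 16 with voom, 19 with only the groups compared, 6 without the 3 libraries and 9 to 26 with 1 left out. For the genotype under the control virus (2) they were 5 with both covariates, 1 with voom, 1 without the 3 libraries and 1 to 2 with 1 left out. For the genotype under the Foxp2 virus (8) they were 13 with a surrogate variable, 13 with the cortical covariate, 15 with both, 15 with DESeq2 and 4 to 8 with 1 left out. For the interaction (0) they were 3 with no filter, 3 with DESeq2, 2 with a surrogate variable, 2 with each covariate fit and 0 to 1 with 1 left out. The cause was not tested, apart from the fewer samples or genes that some settings leave.

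With an estimated correlation 4, 1, 5, 0 and 0 lists were called for the virus in control mice, the genotype under the control virus, the virus in BACHD mice, the genotype under the Foxp2 virus and the interaction, and with fry 5, 1, 7, 0 and 0. With 1 library left out they were 11 to 16, 2 to 12, 11 to 16, 0 to 4 and 0 to 7. For the genotype under the Foxp2 virus, 3 lists were called with the cortical covariate and 5 with both, and for the interaction 6 and 4, and 6 without the 3 libraries. Of the lists that reversed, choroid plexus for the genotype under the control virus was at -0.067 with both covariates, where the test turned. The choroid score is the mean of that same list, so its change follows from the setting. Cortical neurons for the virus in BACHD mice were at -0.072 without the 3 libraries, which were picked as lowest in that list. Huntington model genes for the virus in BACHD mice were at 0.033 and 0.031 with the covariates, and the cause was not tested. The correlation of the virus effects was 0.337 over genes with a mean log2 CPM of at least 3, 0.137 without the 3 libraries and 0.19 to 0.266 with 1 left out. That of genotype and virus in BACHD mice was -0.686 without the 3 libraries, where 2 shared BACHD+Con mice remain and simulated unchanged groups gave -0.658 (-0.679 to -0.639; covariance -0.172 against -0.227 observed over the same genes; the cause was not tested). It was -0.568 to -0.326 with 1 left out, and -0.025, 0.072, 0.061, -0.004, 0.142 and 0.003 with the BACHD+Con mice split 2 and 2, which removes the shared libraries.

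Replicate numbers did not pair the mice: same-number deviations correlated at -0.168 to 0.102, 2 of 16 over 0.1, and 1 library correlated best with its own number. With the replicate block the called genes were 21, 1, 22, 7 and 0 in the order above (Msantd1 lost under the control virus, adjusted p = 0.0623), and 2 lists were called for the genotype under the Foxp2 virus. At this depth 1.5-fold changes were mostly missed in the simulation, 5 of 66 being recovered in control mice.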

Other observations

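The protocadherin families, the B and plasma cell genes and all tests of splits in this part were looked at after the results were seen.

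The neighbouring protocadherin families on the same chromosome were looked at beside the beta cluster. In control mice all 11 tested alpha protocadherins were higher with the Foxp2 virus (median log2 fold change 0.81), 3 of them adjusted over the list alone and 0 over all genes. In BACHD mice 9 of 11 were higher (median 0.41), 1 of them adjusted over the list alone. Of 22 gamma protocadherins 19 were higher in control mice (median 0.23), and Pcdhga3 rose from 18 to 38.7 CPM (adjusted p = 0.0187), while in BACHD mice 14 were higher and 0 passed. Alpha and gamma variants share constant exons, so their counts rest on the variable first exons and are uncertain. Of 6 type IV collagen genes tested, Col4a1 and Col4a2 fell in control mice and Col4a2 in BACHD mice.

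Jchain had 45 reads in Con+Con, 159 in Con+Foxp2, 1 in BACHD+Con and 135 in BACHD+Foxp2, that is 3.62, 12.2, 0.0964 and 11.2 CPM. The other B and plasma cell genes had few reads over all 16 libraries (for example Cd79a 11, Mzb1 19 and Cd22 53), and no list test was possible. Lyz2 followed the same order of groups, at 4.9, 14.9, 1.81 and 11.8 CPM. Both genes were lowest in BACHD+Con, but the antigen presentation list was at 2.87 log2 CPM in both control-virus groups. No uninjected mice were analysed here to set a baseline.

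Whether other splits of the libraries give as many calls was counted for each comparison. For genes, no other split reached the real count for the virus in control mice (31 genes, highest other 4). Nor did any for the virus in BACHD mice (33, highest other 2) or the genotype under the Foxp2 virus (8, highest other 0). The real split was 1 of 35 each time, the smallest share that these splits can give, so the count alone does not exclude chance. Foxp2, which the virus delivers, was among the called genes each time, and Htt was among the 8 for the genotype. For the genotype under the control virus 4 of 35 splits reached the count (2 genes, highest other 355), so it does not speak against chance. The 2 genes, Htt and Msantd1, were higher in every BACHD than in every control library under both viruses (exact permutation p = 0.0286 in each). They were picked from the control-virus comparison, so their separation there adds nothing to the tally. The Foxp2-virus libraries are from other mice, and the separation there does not rest on that choice. For the interaction the real count is 0, which all 100 of 100 groupings reach by construction (highest other 17), so it says nothing about chance. For lists the virus in BACHD mice gave 13, which 1 of 35 splits reached. The highest other gave 12, and leaving out 1 library moved the count between 11 and 16, so a margin of 1 list does not firmly exclude chance. It is not excluded for the virus in control mice (12; 5 of 35, highest other 14), the genotype under the control virus (9; 10 of 35, highest other 18), the genotype under the Foxp2 virus (1; 31 of 35, highest other 11) or the interaction (2; 92 of 100, highest other 21). The split with 355 genes set Con+Con mice 1 and 3 with BACHD+Con mice 1 and 4, the 4 higher in cortical markers, against the rest, which points to a structure of these samples other than genotype.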
